A study of Mus musculus with 4 samples.

How the data were processed

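Total RNA of 4 fibroblast samples, 2 with negative control siRNA and 2 with Xpo5 siRNA, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The deposited scanner files hold the intensity of every spot, extracted with Agilent Feature Extraction 10.5.1.1 per the file headers. Their processed signal is a background-subtracted and spatially detrended intensity on a linear scale, per the file headers. The deposited series table holds log2 values. Set against the scanner values, it is the log2 of the processed signal shifted by 1 constant per array to a common median of 5.33, with 99.3% to 99.4% of probes within 0.001 of that, so that its scale and direction are known and its genes were not centred.

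The log2 processed signal was taken for each spot, minus the 75th percentile of its array over the non-control probes. Each array had 43379 non-control spots, of which 77 to 134 were marked as outliers by the scanner software and left out, and 0 were saturated. Spots of a probe were averaged on the log2 scale to give 41174 probes. A probe was kept when it was well above background on both arrays of at least 1 group, which left 25643. Gene names came from the mouse RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probes, 26690 matched by accession, 5189 by symbol and 952 by a synonym, and 8343 had no match and were not given an official symbol. The 22601 kept probes with a symbol covered 13924 genes, each represented by its probe with the highest mean signal over the 4 arrays. Probe positions are those of the files, on mm9.

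Groups were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with no trend and no block, two-sided, and the Benjamini-Hochberg adjustment at 0.05. Fitted log2 differences are given with their SE. Where a probe was not well above background on either array of a group, the fold is a lower bound. It sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. The 24 gene lists, with markers of 6 other cell types among them, were tested with camera of limma at a preset correlation of 0.01 and the adjustment taken over the lists. Missing values left 13916 genes for that test. An estimated correlation was the alternative, with which 0 of the 24 lists passed and the smallest adjusted p was 0.412. The smallest exact permutation p that 2 arrays against 2 can give is 0.333, so no single value was tested that way.

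The lists, the settings and the rule for named genes were fixed before the data were examined. The rule names Xpo5, up to 12 genes in each direction with the largest changes among those that passed and whose groups did not overlap, filled to 12 by unadjusted p, and for each list up to 4 members with the smallest p. Only genes with official symbols were eligible. Groups did not overlap for 47.6% of the genes, against 33.3% by chance.

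Replicate numbers were read as the 2 independent experiments that the series text names, although the labels do not say in so many words that a number marks the same experiment in both groups. Deviations from the group means correlated at r = 0.451 between arrays of the same number, over 13916 genes, which are not independent replicates. The difference between the siRNAs had the same sign in both experiments for 71.9% of the genes. Each slide held 1 array of each group with different replicate numbers, so that the slide contrast is the residual of the fit with the replicate block, which has 1 residual degree of freedom against 2 without it. Each slide was also scanned as 1 scan. The labels do not say whether the experiments used different embryos, so that the p values measure the spread between these samples.

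The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, other filters on dim probes, every kept probe on its own, the mean of the probes of a gene, an intensity trend, the slide or the replicate number as a block, a threshold of at least 2-fold, each array left out in turn, with the lone array of its group assumed to vary like the others, and the deposited log2 table. On replicate 1 of Xpo5 siRNA a bright patch gave 10 spots a local background more than 5 units above their signal, up to 405379 units, and normexp fitted a background spread of 4569 units there against 0.716 or less on the other arrays. It was therefore also run without the spots marked for uneven local background, which are 23 on that array. The main values do not use this local background. The normexp offset of 50 exceeds the median processed signal of each array, which was 38.5 to 45.6. It therefore shrinks the differences of dim probes by construction. Cx3cr1 lacked a value on 1 array and was left out of the list test, which held the other 15 macrophage markers.

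The planned test of genes by microRNA seed sites in their 3' untranslated regions was not run, because no sequences of these regions were used here. The tests were tested on simulated data made from the gene means and spread of these arrays, with genes that varied independently. In 10 simulations of 13916 genes with 200 changed, the fit without a block found 0% of the 1.5-fold, 11.2% of the 2-fold and 96.1% of the 4-fold changes, with 2.88% of the calls false. The fit with the replicate block found 0.597%, 52.7% and 97.3%, with 6.90% of the calls false. A list shifted by -0.5 passed camera in 10 of 10 simulations with the preset correlation and in 0 of 10 with an estimated one, and no other list passed. As the simulated genes varied independently, this cannot show how often lists of genes that vary together pass falsely with the preset correlation. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading files and drawing.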

Results

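Gene expression was measured in primary embryonic fibroblasts of C57BL/6 mice that had received a negative control siRNA or an siRNA against Xpo5, the gene of the nuclear export factor Exportin-5. The siRNA was given at 60 nM for 12 h, after which the cells were held in 0.2% serum for 48 h, a low level that takes fibroblasts out of the cell cycle, and then in 20% serum for 24 h with a second dose. The comparison asks how the loss of Exportin-5 alters the transcripts of fibroblasts that are returning to the cycle. Each siRNA group held 2 samples, from 2 independent experiments, and each sample was hybridised to its own 1-colour array. Between 62.4% and 65.0% of the spots were well above background on each array, and the number of arrays limits the precision of every value.

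Xpo5 itself fell by 3.23 ± 0.12 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 0.0107), which left 10.7% of the control signal. Its log2 signal relative to the 75th percentile of the array was 1.31 and 1.26 with control siRNA and -1.95 and -1.93 with Xpo5 siRNA. This probe lies on chromosome 17 at 46378755 to 46378814 of the mouse mm9 build, as the files give it. A second probe, at 46379784 to 46379843, differed by -3.08, and the third, a much dimmer one at 46345161 to 46351152, by -1.34. The fourth was well above background on 1 of the 4 arrays and was not used. The fall was -3.21 within slide 1 and -3.25 within slide 2, and its adjusted p was 0.0295 with the slide as a block. The limma adjusted p was above 0.05 when the probes of a gene were averaged, at -2.55 and 0.149, and when dim probes were kept, at 0.168, and over all alternatives it went from 0.00136 to 0.595.

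**Figure D1:**
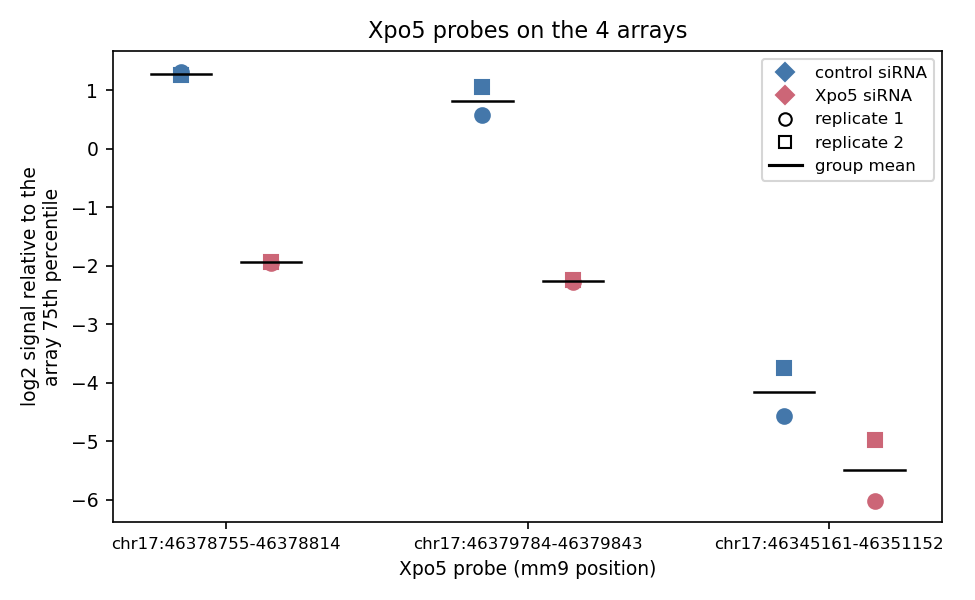
Log2 signal of the 3 Xpo5 probes that were well above background on all 4 arrays, relative to the 75th percentile of each array, with 1 point per array and a line at each group mean. The brightest probe, on the left, reads 1.31 and 1.26 with control siRNA and -1.95 and -1.93 with Xpo5 siRNA.

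Beyond Xpo5, the transcripts of DNA replication and cell division were lower, and those of macrophages, of the interferon response and of neural cells were higher, with Xpo5 siRNA. The sizes were moderate, with list medians between -0.50 and 0.64 on the log2 scale. These calls of 9 lists come from camera with its preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.412. That setting also takes fewer degrees of freedom, and it passed a list shifted by -0.5 in 0 of 10 simulations. With the preset correlation, the interferon and neural lists lost their calls under some other settings. The macrophage and nuclear transport lists kept theirs under 14 of 15. Single genes mostly did not reach the threshold. Of 13924 genes tested, 3 passed limma at an adjusted p under 0.05, 2 higher and 1 lower, while 2043 had an unadjusted p under 0.05. The 2 that rose were Ugt2b38, a glucuronosyltransferase gene, at least 2.58-fold (adjusted p = 0.0107), and Cyp2b13, a cytochrome P450 gene, at least 1.88-fold (adjusted p = 0.0334), both not well above background on either control array. Neither passed when dim probes were kept or an intensity trend was fitted, and their differences were 0.60 and 0.43 with normexp background correction repaired for uneven spots. The split was 3 higher and 5 lower with median scaling, and 1 higher and 2 lower with quantile normalization. With the replicate number as a block, which takes out the difference between the experiments, 608 genes passed in limma, 415 higher and 193 lower, and all 3 genes named above were among them. Of these 608, 166 differed at least 2-fold, 123 upward and 43 downward, or 104 and 39 with lower bounds in place of folds, and 60 were well above background on neither array of 1 group. With the slide as a block, 4 genes passed. Without replicate 1 of control siRNA 71 genes passed, without replicate 2 of control siRNA 114, without replicate 1 of Xpo5 siRNA 90 and without replicate 2 of Xpo5 siRNA 43, where the lone array of a group is assumed to vary like the others.

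Among the named genes with a higher signal, the next 10 by p after Ugt2b38 and Cyp2b13 passed when the replicate block was added and did not pass before. Of these Olfml1 also passed with median scaling, at an adjusted p of 0.0145 in limma, and Ndrg4 with repaired normexp, at 0.0348, where the differences of Myh7, Olfml1, Egflam, Slc2a5 and Timp4 shrank to 0.96, 0.40, 0.56, 0.47 and 0.46, and those of Atp8b4, Cd244a and Clec1a to 0.21, 0.31 and 0.32. Myh7, a slow muscle and cardiac myosin heavy chain, differed by 1.90 ± 0.14 on the log2 scale (SE, limma adjusted p = 0.0922, and 0.0437 with the block). The others with signal in both groups were Nkain4 at 1.61, Egflam, an extracellular matrix gene of the retina and other tissues, at 1.28, the fructose transporter gene Slc2a5 at 1.33, and Ndrg4 at 1.37. Timp4, an inhibitor of matrix metalloproteinases, differed by 1.51 and was well above background on 1 of the 2 control arrays. Olfml1, Atp8b4, Cd244a, an immune receptor gene, and Clec1a were not well above background on either control array, and were at least 1.53, 1.25, 2.02 and 2.38-fold higher with Xpo5 siRNA. All of these had block-adjusted p values of 0.0437.

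Among the genes with a lower signal, Cdhr4 and Spag11a were not well above background on either Xpo5 siRNA array. They were at least 6.53-fold and 2.51-fold lower there (limma adjusted p = 0.0634 and 0.0922, and 0.0437 and 0.00678 with the replicate block). Cdhr4 also passed with the slide as a block, at 0.0156, and both passed with median scaling, at 0.00587. Ostf1 passed with repaired normexp, at 0.0327, and with Acsl4 and Cdhr4 under an intensity trend, at 0.0447. With repaired normexp the differences of Cdhr4, Spag11a, Myb, Klrg1 and Flt4 shrank to -0.68, -0.43, -0.20, -0.08 and -0.23. Myb, the gene of a transcription factor of dividing progenitor cells, and Klrg1 were at least 2.46-fold and 1.11-fold lower, again at background with Xpo5 siRNA. Genes with signal on all 4 arrays were Acsl4, which activates long-chain fatty acids, at -1.52 ± 0.14, Ostf1 at -1.51 ± 0.13, and Arl2bp at -1.53 ± 0.17. Cetn3, a centrosome gene, differed by -1.18, the histidyl-tRNA synthetase gene Hars by -1.15, the receptor gene Flt4 by -1.14 and Sprr1a by -1.04. Other probes of Acsl4, Arl2bp and Hars read -0.29, -0.37 and -0.34, and the means over the probes were -0.91, -0.95 and -0.75. Without the block none of those with signal on all arrays passed, at limma adjusted p values of 0.113 to 0.144, and with it each passed at 0.0437, as Myb and Klrg1 did.

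The G1/S list, which holds E2F targets and genes of DNA replication, fell as a group. Its median was -0.50 on the log2 scale over 48 genes, 47 of which were lower (camera adjusted p = 1.71e-19, and 0.550 as the adjusted p with an estimated correlation). Within the experiments the median was -0.49 and -0.55, and within the slides -0.40 and -0.58, and with the slide as a block the adjusted p was 2.49e-19. Over all genes tested 0 members passed in limma without a block and 8 fell with the replicate block, with 31 at an unadjusted p under 0.05. Adjusted over the list alone, 26 fell without the block and 38 with it. The 4 members with the smallest p were Ccne2, a cyclin of S phase entry, at -0.83 ± 0.12, Cdc6, which loads the replicative helicase, at -0.84 ± 0.16, the repressor E2f7 at -0.81 ± 0.16 and Fbxo5, an inhibitor of the anaphase-promoting complex, at -0.68 ± 0.13. The other probe of Cdc6 read -0.30.

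The G2/M list, of mitotic genes, fell by a median of 0.34 over 55 genes, 53 of them lower (camera adjusted p = 1.23e-11, and 0.559 as the adjusted p with an estimated correlation). It stood at -0.24 and -0.40 within the experiments and at -0.28 and -0.37 within the slides, with an adjusted p of 8.23e-11 with the slide as a block. In limma 1 member, Cdca3 at -0.65 ± 0.15, fell with the replicate block over all genes tested and 0 did so adjusted over the list alone. Without the block 0 passed, against 20 at an unadjusted p under 0.05. Dlgap5 read -0.51, with its other probe at -0.07, Ckap2 -0.46, with its other probe at -0.23, and Ccnb1, the cyclin of mitotic entry, -0.47. Replication histones fell by a median of 0.31 over 18 genes (camera adjusted p = 0.000791, and 0.681 as the adjusted p with an estimated correlation), at -0.17 and -0.35 within the slides and with an adjusted p of 0.00105 with the slide as a block. In limma 1 histone gene, H3c1 at -0.77, passed with the replicate block, and 7 fell and 1 rose adjusted over the list alone. H3c1 was chosen after its values were seen. By the naming rule, the histone genes with the smallest p were H2ac15 at -0.66 ± 0.16, H1f1 at -0.51 ± 0.13, H2ac13 at -0.48 ± 0.15 and H2bc4, which was higher, at 0.44 ± 0.12.

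**Figure D2:**
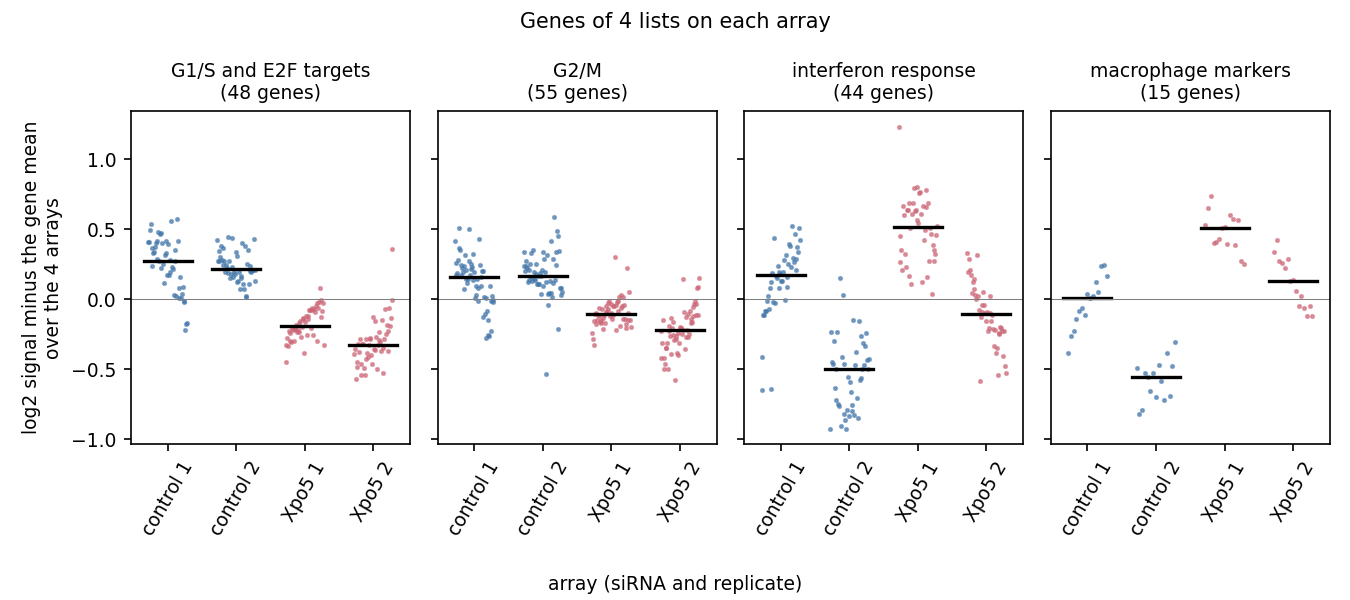
Log2 signal of each gene of 4 lists on each array, relative to the mean of that gene over the 4 arrays, with 1 point per gene and a line at the median. The medians of the 48 G1/S genes and of the 55 G2/M genes sit lower on both Xpo5 siRNA arrays than on both control arrays, while the 44 interferon genes also differ between the replicates.

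Genes of ribosome biogenesis, many of them targets of MYC, fell by a median of 0.23 over 44 genes, with 42 lower (camera adjusted p = 1.58e-07, and 0.412 as the adjusted p with an estimated correlation). The shift was -0.24 and -0.29 within the slides and had an adjusted p of 9.17e-07 with the slide as a block. In limma 0 members passed over all genes or adjusted over the list alone, with or without the replicate block, while 11 had an unadjusted p under 0.05. Nop16 read -0.91 ± 0.25, Lyar -0.52, Rrp9 -0.42 and Rrs1 -0.53. Genes of cholesterol and fatty acid synthesis fell by a median of 0.23 over 33 genes (camera adjusted p = 2.26e-05, and 0.412 as the adjusted p with an estimated correlation), at -0.20 and -0.28 within the slides and with an adjusted p of 4.58e-05 with the slide as a block. Of these, Sc5d at -0.76 ± 0.13, a late enzyme of cholesterol synthesis, and Elovl6 at -0.70 ± 0.13, which lengthens fatty acids, fell in limma adjusted over the list alone, and over all genes with the replicate block. Idi1 read -0.44, with its other probe at -0.06, and Pmvk -0.35.

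Nuclear transport genes other than Xpo5 fell by a median of 0.16 over 30 genes (camera adjusted p = 0.00867, and 0.681 as the adjusted p with an estimated correlation), at -0.06 and -0.28 within the slides and with an adjusted p of 0.0145 with the slide as a block. In limma 0 members passed over all genes or adjusted over the list alone, with or without the replicate block, while 7 had an unadjusted p under 0.05. Xpo1, the main exporter of proteins, read -0.46 ± 0.14, Rangap1 -0.51 and Tnpo1 -0.38, with its other probe at -0.15, while the importin gene Ipo8 read 0.51. Other probes of Xpo1 and Rangap1 included 1 each of the opposite sign. Without replicate 1 of control siRNA this list no longer passed, at a median of -0.13 and a camera adjusted p of 0.0714, and without replicate 2 of control siRNA the median was -0.23.

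Macrophage markers rose by a median of 0.64 over 15 genes, all of them higher in both experiments (camera adjusted p = 1.03e-05, and 0.681 as the adjusted p with an estimated correlation). The medians were 0.49 and 0.74 within the experiments, and 1.03 and 0.10 within the slides, whose arrays differ in replicate number, with an adjusted p of 9.17e-07 with the slide as a block. In limma Laptm5 at 0.87 ± 0.14 and Aif1 at 1.08 ± 0.23 rose adjusted over the list alone. With the replicate block 13 rose adjusted over the list alone and 4 over all genes, the other 2 being Adgre1, a surface receptor gene of macrophages, at 1.02 ± 0.26 and Itgam at 0.64, the last chosen after its values were seen. Lyz1 read 0.66. Without replicate 2 of control siRNA the median was 0.29 and the camera adjusted p 0.00754. Macrophage genes were also higher in replicate 1 than in replicate 2 by a median of 0.56 with control siRNA and 0.37 with Xpo5 siRNA.

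Interferon-stimulated genes rose by a median of 0.46 over 44 genes, 38 of them higher (camera adjusted p = 0.000250, and 0.681 as the adjusted p with an estimated correlation). The medians were 0.40 and 0.43 within the experiments, with an adjusted p of 3.96e-08 with the replicate block. They were 1.02 within slide 1 and -0.26 within slide 2, where the arrays compared differ in replicate number and so carry the gap between the experiments, with an adjusted p of 3.84e-05 with the slide as a block. Their level in replicate 1 exceeded that in replicate 2 by a median of 0.76 with control siRNA and 0.66 with Xpo5 siRNA, a gap larger than that between the siRNAs. Without replicate 1 of Xpo5 siRNA the median was 0.13 (camera adjusted p = 0.481), and without replicate 2 of control siRNA it was 0.10 (camera adjusted p = 0.256), while without replicate 1 of control siRNA it was 0.73 and without replicate 2 of Xpo5 siRNA 0.75. With normexp background correction, which failed on 1 array, the median turned to -0.69. In limma 0 members passed without the block, over all genes or adjusted over the list alone, against 5 at an unadjusted p under 0.05. With the replicate block 5 rose over all genes, and 29 rose and 1, Ccl5 at -0.47, fell adjusted over the list alone. Those that rose over all genes were Mx1, an antiviral GTPase, at 1.57 ± 0.32, and, chosen like Ccl5 after their values were seen, Oas1a at 0.71, Oas3 at 0.73, Zbp1 at 0.71 and Iigp1 at 0.65. Irf7 read 0.65, Trim25 0.56, with its other probe of the opposite sign, and Ddx58 0.57. Macrophage markers, which moved with this list, had the shift of 0.64 given above.

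Neural markers rose by a median of 0.42 over 11 genes (camera adjusted p = 0.0294, and 0.559 as the adjusted p with an estimated correlation), at 0.39 within each slide and with an adjusted p of 0.0145 with the slide as a block. In limma Nefl, a neurofilament gene, at 1.14 ± 0.17, Map2 at 0.65 ± 0.13 and S100b at 0.79 ± 0.22 rose and Nes at -0.45 ± 0.13 fell adjusted over the list alone. With the replicate block 3 rose over all genes. The list no longer passed camera with quantile normalization, with dim probes kept, with an intensity trend or with repaired normexp, at adjusted p values of 0.0874, 0.0504, 0.0758 and 0.0871. Without replicate 1 of control siRNA the adjusted p was 0.0746, and without replicate 2 of Xpo5 siRNA the median was 0.28.

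The other 15 lists did not pass camera. The closest were the host transcripts of microRNAs, with a median of 0.24 over 11 genes (camera adjusted p = 0.0539), extracellular matrix genes at 0.15 over 49 (adjusted p = 0.0595) and skeletal muscle markers at 0.31 over 13 (adjusted p = 0.0668). With the replicate block these 3 passed, at adjusted p values of 0.0281, 0.0368 and 0.0133, against an adjusted p = 0.681 for each with an estimated correlation and no block. The host transcripts H19, Meg3, Rian and Mirg read 0.56 ± 0.23, 0.55 ± 0.23, 0.46 ± 0.21 and 0.45 ± 0.23, with the probes of Meg3 between 0.10 and 0.55. Their list stood at 0.37 and 0.15 within the slides, and passed with the slide as a block at 0.0380. The matrix list stood at 0.22 and -0.00 within the slides and the muscle list at -0.12 and 0.52. Adjusted over the list alone in limma, the matrix genes Fbln2 at -1.24 ± 0.15 and Plod2, a collagen lysyl hydroxylase, at -1.12 ± 0.18 fell and the muscle genes Ttn, at background with control siRNA and at least 1.52-fold higher, and Tnnt3, at 0.74 ± 0.14, rose. Col7a1 at 0.72, Fmod at 0.81 and Myh8 at 1.46 passed over all genes with the replicate block. The host list passed without replicate 1 of control siRNA, at 0.35 and 0.00976, and the muscle list without replicate 1 of Xpo5 siRNA, at 0.41 and 0.0298, and without replicate 2 of control siRNA, at 0.37 and 0.0398.

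Known targets of let-7 and other fibroblast microRNAs, which Exportin-5 acts upstream of, had a median of -0.02 over 48 genes, with 23 higher and 25 lower (camera adjusted p = 0.444). In limma 0 passed without the block, with 10 at an unadjusted p under 0.05, and with the replicate block 4 passed over all genes, while 3 rose and 6 fell adjusted over the list alone. Among them Cav1, a gene of caveolae, rose at 0.66 ± 0.13, and Hmga2, a well known let-7 target, at -0.77 ± 0.17, with a probe as low in size as -0.31, and Dnmt3b, a DNA methyltransferase gene, at -0.71 ± 0.16 fell. Genes of the microRNA pathway had a median of -0.07 over 27 genes (adjusted p = 0.119), and passed without replicate 2 of control siRNA, at -0.21 and 0.0435. Of these Tnrc6b, a partner of the Argonaute proteins, read -0.78 ± 0.14 and passed over all genes with the replicate block, but 1 of its 6 kept probes had the opposite sign, at 0.71. Ago2 read -0.44, with 1 of its 4 kept probes of the opposite sign, at 0.05, and the exonuclease gene Xrn1 read 0.84.

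Serum-response genes had a median of -0.08 over 38 genes (camera adjusted p = 0.122, and 0.0383 without replicate 1 of Xpo5 siRNA), with Areg, an EGF receptor ligand, at -1.08 ± 0.19, Phlda1 at -0.62 and Myc at -0.55. Areg passed over all genes with the replicate block. G1 regulators and quiescence genes had a median of 0.01 over 40 genes (adjusted p = 0.920), with Mxi1, a MAX-binding repressor, at -1.07 ± 0.13, which fell adjusted over the list alone in limma, and Btg2 at -0.55, Cdkn2b at 0.57 and Mxd4 at 0.71, the last with 2 other probes of the opposite sign. The hypoxia and glycolysis list, which also holds Mxi1, had a median of -0.07 over 32 genes (adjusted p = 0.552), with Pdk1 at 0.57 and its other probe at 0.19. The p53 targets stood at -0.02 over 35 genes (adjusted p = 0.552), with Pmaip1 at -0.60 and Bbc3 at 0.54. ER stress genes stood at -0.01 over 42 genes (adjusted p = 0.552), with Creld2 at -0.37, and contractile genes at 0.00 over 37 genes (adjusted p = 0.694), with Itga11 at 0.63 and Ankrd1 at -0.58. Inflammatory secreted factors stood at 0.06 over 31 genes (adjusted p = 0.552), with Il11 at 0.85 and Tnf at 0.79, which rose, and Mmp10 at -0.68, which fell, over all genes in limma with the replicate block.

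Of the remaining marker lists, adipocyte markers had a median of 0.24 over 8 genes (camera adjusted p = 0.109, 0.0251 without replicate 1 of control siRNA and 0.0231 without replicate 2 of Xpo5 siRNA), endothelial markers 0.18 over 9 (adjusted p = 0.413) and epithelial markers -0.01 over 7 (adjusted p = 0.509). Adjusted over the list alone in limma, the lipid droplet gene Plin4 at 1.44 ± 0.21, the VEGF receptor gene Kdr at 1.19 ± 0.17 and Tek, an angiopoietin receptor gene, at 0.63 ± 0.14 rose. Krt5 read -0.92 and Dsp -0.46. Over the 24 lists, 692 different members were measured, of which 0 passed over all genes without a block in limma, 152 had an unadjusted p under 0.05, and 43 passed with the replicate block, 23 upward and 20 downward.

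**Figure D3:**
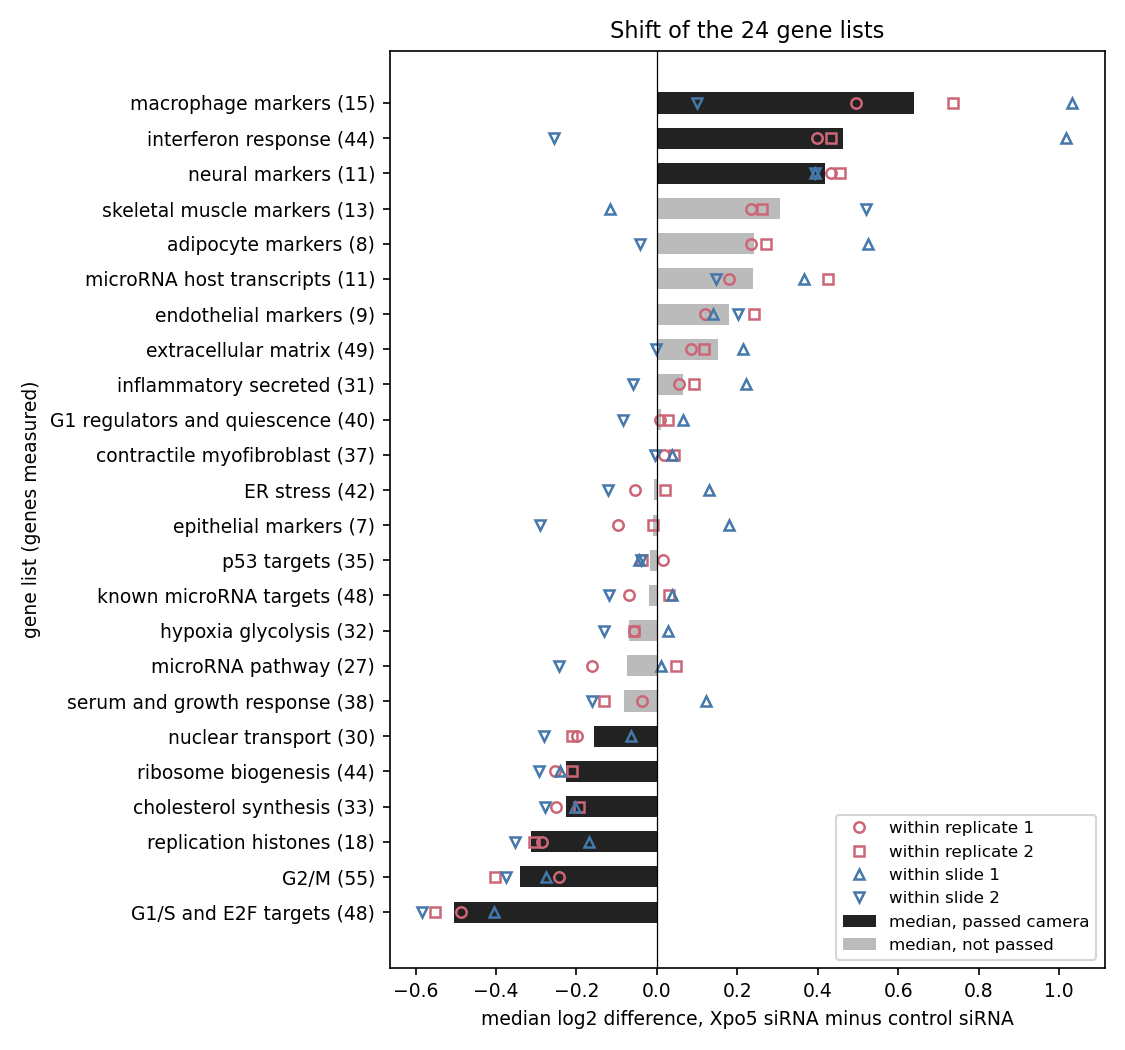
Median log2 difference between Xpo5 siRNA and control siRNA for the 24 gene lists (bars, black where the list passed camera), with the median within each replicate number and within each slide as points. The G1/S list lies below 0 in both replicates and on both slides, from -0.40 to -0.58, and the interferon list goes from 1.02 on slide 1 to -0.26 on slide 2.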

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

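The replicate block combined with the filter on all 4 arrays or with a 2-fold threshold, and normexp without spots of uneven local background, were alternatives chosen after seeing the data. The others were planned. The planned test of microRNA seed classes, with its alternatives, was not run, because no 3' untranslated regions were used here.

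The G1/S, G2/M, ribosome biogenesis, cholesterol synthesis and replication histone lists kept their direction and passed under all 15 other settings run with the preset correlation. The G1/S median went from -1.12 to -0.44 and its largest camera adjusted p was 1.92e-07. The -1.12 and that p come from normexp, which failed on 1 array and where 14 lists were lower. Over all alternatives, lists kept their side of the threshold in 331 cases, gained a call in 32, lost one in 18 and turned in 3. Named genes kept their side in 1612, gained in 89 and lost in 10. Among the kept, the sign changed in 23 cases for lists and 36 for genes, all without a call, and all 36 for genes under normexp. The extracellular matrix, microRNA host and skeletal muscle lists kept their side under 8, 7 and 9 of the 15. For effects that were moved or lost below the cause was not tested unless it is given.

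With an estimated correlation 0 lists passed camera, 0 higher and 0 lower, against 9 with the preset one. By construction the medians stayed, at -0.50 for G1/S, -0.34 for G2/M, -0.23 for ribosome biogenesis, -0.23 for cholesterol synthesis, -0.31 for replication histones, -0.16 for nuclear transport, 0.64 for macrophage markers, 0.46 for interferon genes and 0.42 for neural markers. This setting also takes the 2 residual degrees of freedom of the arrays in place of those over genes. The estimated correlation was -0.006 for ribosome biogenesis, -0.019 for cholesterol synthesis and -0.020 for neural markers. These lie below the preset 0.01, so that their own correlation did not end those calls. It was 0.19 for G1/S, 0.16 for G2/M, 0.22 for replication histones and 0.15 for nuclear transport. For macrophage markers it was 0.95 and for interferon genes 0.83. These estimates exceed the preset 0.01, and a correlation above the preset makes the p values of the preset test too small. Which part ended the calls of the other lists was not tested.

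With normexp 0 genes passed limma, 0 higher and 0 lower, with 12 at an unadjusted p under 0.05, and 17 lists passed, 14 of them lower. Xpo5 was at -2.08 (adjusted p = 0.595), the median of all genes moved by -0.17, and the interferon, matrix and contractile lists turned to -0.69, -1.08 and -1.05, while macrophage markers at 0.53 no longer passed (adjusted p = 0.0693). The cause was the fitted background spread of 4569 units on 1 array. Without the spots of uneven local background, 3 genes passed, 1 higher and 2 lower, 1 of them also called in the main setting, and neural markers at 0.21 did not (adjusted p = 0.0871). In both normexp settings the offset shrinks the differences of dim probes by construction.

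Quantile normalization gave 1 gene higher and 2 lower, and neural markers at 0.33 (adjusted p = 0.0874). Median scaling and the series table each gave 8 genes, 3 higher and 5 lower, and 5 lists higher. With dim probes kept 0 genes passed limma, 0 higher and 0 lower, against 1692 at an unadjusted p under 0.05. More genes were tested there, Xpo5 was unchanged at -3.23 (adjusted p = 0.168) and neural markers stood at 0.39 (adjusted p = 0.0504). With probes well above background on all 4 arrays 1 gene passed, 0 higher, since that filter removes Ugt2b38 and Cyp2b13, and 5 lists were higher. The intensity trend gave 0 genes higher and 4 lower, and neural markers at 0.42 (adjusted p = 0.0758). The mean of the probes of a gene gave 1 gene, 1 higher and 0 lower, Xpo5 at -2.55 (adjusted p = 0.149) and 5 lists higher. Testing every kept probe gave 0 probes, 0 higher and 0 lower in limma. At least 2-fold left the 3 genes.

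The slide block gave 4 genes, 2 of them lower. The replicate block gave 608 genes, 415 higher and 193 lower, and 6 lists higher. With it 12 lists passed, 9 of them also called without it, so that it ended no call of a list. With the filter on all 4 arrays it gave 1369, 863 higher and 506 lower, and at 2-fold 166, 123 higher and 43 lower. Without 1 array, 43 to 114 genes passed, 15 to 82 higher and 7 to 87 lower. The interferon list then went from 0.10 to 0.75, nuclear transport from -0.23 to -0.12 and neural markers from 0.28 to 0.52. Of the 13924 genes tested, 132 were at background on both arrays of 1 group, so that background bears on few of the single genes.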

Other observations

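The test of imprinted genes, whose list was written once the values of H19, Meg3, Rian and Mirg were known, and the tests on probes detected with one siRNA only were written down before their results were seen, and the other tests in this part were chosen after.

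The G1/S genes lay lower than the mitotic genes with Xpo5 siRNA, with a mean log2 difference of -0.49 over 48 genes against -0.31 over 55 (two-sided permutation p = 1e-05, the smallest that 100000 permutations give, over genes, which are not independent replicates). Among the imprinted genes, Phlda2 read 0.63 ± 0.15, Igf2, a fetal growth factor gene, 0.57 ± 0.19, Cdkn1c, an inhibitor of cyclin-dependent kinases, 0.48 ± 0.21, Peg3 0.45 ± 0.16 and Dlk1 0.44 ± 0.23, and Peg10 read -1.01 ± 0.36 and Peg12 -0.72 ± 0.19. These were chosen after their values were seen, and of them Peg10 alone passed limma with the replicate block (adjusted p = 0.0486).

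H19, Meg3, Rian and Mirg, which are imprinted host transcripts of microRNAs, read higher with Xpo5 siRNA, and a candidate explanation is a wider rise of imprinted genes. With H19, Meg3, Rian and Mirg left out, the median log2 difference of 28 other imprinted genes was 0.29, above the range of -0.10 to 0.13 that holds 95% of 10000 random lists matched on mean signal, and 20 of the 28 were higher. No random list lay as high (one-sided permutation of genes within bins of mean signal, p = 1e-04, the smallest they can give). It was 0.29 within slide 1 and 0.05 within slide 2, and genes of a list that vary together make the random range too narrow. The result is consistent with the hypothesis, which stays untested in other samples.

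The fall of the cell cycle genes was set against 2 technical explanations, with the G1/S list alone. Each slide held 1 array of each siRNA, so that an effect shared by the arrays of a slide cancels between the groups. An intensity-dependent bias would move random lists of like signal, but the list median of -0.50 lay below their 95% range of -0.10 to 0.05. Dilution by RNA of other cells would lower the matrix and contractile genes of fibroblasts too, but their means were 0.10 and 0.05 against -0.49 for the G1/S list (larger permutation p over genes, which are not independent replicates, = 1e-05, the smallest they can give), and within the slides their medians were 0.22 and -0.00 for matrix and 0.04 and -0.01 for contractile genes. Variation between samples stays open, with 2 arrays per group. The loss of the call with an estimated correlation (camera adjusted p = 0.550) cannot decide this, as that setting passed a shifted list in 0 of 10 simulations. An effect of the loss of Xpo5 stays open as a hypothesis, beside an effect of the siRNA sequence on other targets, which was not tested.

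Macrophage markers and interferon-stimulated genes were both higher with Xpo5 siRNA. Against a lower share of fibroblasts, which would raise the markers of other cell types alike, macrophage markers had a mean log2 difference of 0.60 against 0.24 for the markers of the 5 other cell types (permutation p = 0.0138, and 0.998 within slide 2, whose arrays differ in replicate number). Epithelial markers had a mean of -0.20 but a median of -0.01 over 7 genes. The means of the 6 marker lists lay apart over all arrays (permutation p = 0.0216 over genes, which are not independent replicates) and in experiment 1 (permutation p = 0.0262) but missed the threshold in experiment 2 (permutation p = 0.0509). Within the slides the permutation p was 0.0116 on slide 1 and 0.283 on slide 2. A lower share of fibroblasts is thus weakened at most and stays open. RNA of more macrophages could carry the interferon-stimulated transcripts with it, and their median minus that of the macrophage markers was -0.18 ± 0.08 (SE over genes), as that explanation needs. That too stays open, beside an interferon response of the fibroblasts, since all 15 macrophage markers and all 44 interferon genes, 0 of which another list holds, were well above background in the control cells, and the labels name no sort, while Lyz2, a transcript abundant in macrophages, read 5.42 and 4.95 with control siRNA and 5.92 and 5.73 with Xpo5 siRNA (log2, relative to the 75th percentile).

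Ugt2b38 and Cyp2b13 belong to the 282 probes that were well above background on both arrays of one siRNA and neither of the other, 211 with Xpo5 siRNA and 71 with control siRNA. Splitting the same arrays by slide gave 309 such probes and by replicate number 245, so that the ratio of the siRNA split to the larger of these was 0.913. This ratio lay below the bound set beforehand for noise near background, so that it gave no sign against that explanation. The replicate split can also hold differences between the experiments. The slide split cannot, as each slide held arrays of both experiments, though it can hold differences between the slides. Noise near background stays open. Where such a gene had another probe, that probe moved the same way in 74.5% of 94 genes (70 of 94, exact binomial p = 2.20e-06 against 50%). That share was just short of the 75% set beforehand as the bound. The 50% assumes that dim probes did not shift together, whereas 211 of the 282 were detected with Xpo5 siRNA. Faults of single probes thus stay open too.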
